A study of Homo sapiens with 2 samples.

How the data were processed

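The study hybridised 2 two-colour oligonucleotide arrays, 1 per cell line, from human cancer cells transfected with 25 nM of a synthetic miR-125b precursor (pre-miR-125b) or of a control precursor (pre-control). RNA was taken 12 h after transfection from MCF-7 and 24 h after transfection from MDA-MB-435, per the labels' protocols. Per the labels, the RNA was amplified by the Eberwine method and copied into labelled DNA with Klenow enzyme; the pre-miR-125b sample carried Cy3 and the pre-control sample Cy5 on both arrays. The dyes were not swapped on any array, so a dye bias of a probe cannot be separated from an effect of the precursor. Cell line and time after transfection differ together.

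Each array file held 23232 spots in 48 blocks. Per the file headers, the deposited intensity columns give a whole-number spot intensity per dye, and some values lie at or below 0 (458 gene spots in at least 1 channel on the MCF-7 array and 145 on the MDA-MB-435 array), which is what a background subtraction before deposit leaves. The scanner and its software are not given in the sources used here. Per the file headers, the deposited ratio column is a normalized ratio of pre-miR-125b over pre-control; the method is not given in the sources used here. The authors' series table holds log2 values equal to the log2 of that ratio on both arrays, with medians of −0.02 in MCF-7 and −0.01 in MDA-MB-435, so its scale and direction were settled by this match. The build behind the files' chromosome column is not given in the sources used here, and no coordinates are reported.

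The planned normexp background correction was not applied, because the intensity columns were already corrected. The planned background rule needed a background or flag column; in its place, a background limit was set per channel at the median plus 2 robust SDs of the 559 empty spots. The limits were 112 (pre-miR-125b) and 82.3 (pre-control) on the MCF-7 array and 113 and 118 on the MDA-MB-435 array. Of 192 spots of negative control oligonucleotides, 6 lay above the limit in at least 1 channel on the MCF-7 array and 1 on the MDA-MB-435 array. Within each array, a loess curve of the log2 ratio of pre-miR-125b over pre-control against mean brightness (span 0.3, 4 iterations) was fitted to the deposited intensities above 0, with control and empty spots given no weight. Intensities under the limit were then set to it, and the curve at the resulting brightness was subtracted from the log2 ratio. The unnormalized median log2 ratio of gene spots was 0.29 in MCF-7 and −0.04 in MDA-MB-435. The computation used limma 3.58.1 in R 4.3.3 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9. Spots of a probe were averaged. A probe counted where it lay above the limit in at least 1 channel, and where it did so in 1 channel only its ratio rests on the limit and on the curve at the dim end, so it is given with its value under a curve per block and not as a fold.

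The 21329 gene probes were named through a RefSeq gene table of assembly GRCh38.p14, used for names alone. It gave 15952 probes 1 gene each, 15759 by Entrez ID, 80 by symbol, 59 by an older symbol and 54 by RefSeq accession. A further 293 probes matched several genes and 5084 had no name; these entered counts of probes and were not named. The named probes covered 14933 genes. For a gene with several probes, the probe brightest over both arrays was used.

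With 1 array per line, no replicate check or p-value was possible. Size was judged by a rule, an absolute log2 ratio of at least 1 (2-fold). The 27 gene lists were drawn from general knowledge and fixed before the data were examined (the reported targets include STARD13, which later work on this transfection system reported), and each list's median was placed among 10000 random lists of the same size matched on brightness in 10 bins. A list stands apart where its percentile is under 2.5 or within 2.5 of 100. Among 26 lists with no effect, and with members that vary independently, about 1.3 would. Members at least 1.5-fold higher or lower were counted, and lists needed at least 8 measured members. These percentiles describe the arrays and are not tests of the conditions. Brightness between lines was compared after quantile scaling of the arrays' mean brightness, with channels under the limit set to it.

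The named genes were fixed by a rule written before the data were examined. The rule took, per array, the 12 highest and 12 lowest named genes above background in both channels and brighter than the median counted probe. It then took up to 10 genes per direction past 2-fold on both arrays, the 4 members furthest in the list's direction of each list that stands apart, and STARD13, BAK1, ETS1, ERBB2, ERBB3 and TP53. Y-linked genes and XIST were left out.

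Simulated data used 1 noise SD per array at every brightness, 0.33 for MCF-7 and 0.34 for MDA-MB-435. In them, all probes changed by 2 on the log2 scale were recovered past 2-fold on both arrays. Of probes changed by −1.5, 84% were recovered in the MCF-7 simulation and 96% in the MDA-MB-435 simulation; of those changed by 1.5, 92% and 94%. Unchanged probes passed 2-fold in 34 of 15533 cases (0.219%) and 32 of 15669 cases (0.204%). The real robust SD was 0.41 among the dimmest counted probes and 0.27 among the brightest in MCF-7. In MDA-MB-435 it was 0.37 and 0.29. The changed probes were drawn only from those above the limit in both channels and brighter than the median of these. The rates of recovery thus do not cover dim probes or probes at the background limit. The unchanged probes included dim ones, but their simulated noise was no wider there. Simulated lists of 30 genes shifted by −0.2 stood apart in 78 of 100 draws for MCF-7 and 75 of 100 for MDA-MB-435, against 6 and 3 of 100 with no shift. The simulated genes varied independently, so these rates do not cover real lists whose members vary together.

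Precision on an array was read from probes printed 17 times. Of 12 such probes, 10 were above background on the MCF-7 array and 9 on the MDA-MB-435 array. The median SD of their spots was 0.13 on the log2 scale on both, which covers spot-to-spot error only. These probes were bright. The dimmest had a median pre-miR-125b intensity of 1828 in MCF-7 and 3272 in MDA-MB-435, against 327 and 302 over gene spots. The value thus does not cover dim probes. The number of arrays limits the precision of every value. The alternatives tried were plain ratios without the floor, median centring, a loess curve per block, the authors' ratios, a stricter brightness filter, no filter, a rule of local SDs (the limit that leaves out 2.5% of a normal spread on each side) over windows of 200 probes, the median over a gene's probes, quantile scaling of all channels and the reported targets without STARD13. Added after seeing the data were an offset of 50, a background limit from the spots of 50% DMSO, and leaving out blocks 1 to 8. The planned search for miR-125b sites in 3′ UTRs was not run, because no 3′ UTR sequences were given; sites in the probes' own oligonucleotides, mostly 69 bases long, were searched in their place, a choice made after seeing the data.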

Results

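Gene expression was measured in 2 human cancer cell lines after transfection with pre-miR-125b, a synthetic precursor of the microRNA miR-125b, or with a control precursor. MCF-7 is an oestrogen receptor-positive line with features of luminal breast epithelium, and MDA-MB-435 was described by the submitters as a metastatic breast cancer line. Each line was represented by 1 two-colour array that compared both transfections directly, at 12 h in MCF-7 and 24 h in MDA-MB-435. Of 21329 gene probes, 16031 lay above background in at least 1 channel on the MCF-7 array and 15991 on the MDA-MB-435 array. All ratios are log2 of pre-miR-125b over pre-control after loess normalization of the deposited intensities. There are no replicates, so no value has a replicate check. Spots of the same probe within an array had a median SD of 0.13 in log2 on both arrays, read from a few probes brighter than most. It ranged from 0.07 to 0.33 in MCF-7 and from 0.09 to 0.15 in MDA-MB-435, and it does not cover dim probes.

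The cell lines differed as their lineage markers would separate them. Luminal epithelial genes were brighter on the MCF-7 array by a median of 4.68 in log2, and 14 of 16 measured members were at least 2-fold brighter there. Among members above background in both channels of both arrays, the adhesion gene CDH1 was brighter by 6.49 and KRT18, an epithelial keratin, by 2.57. In MCF-7, KRT18 lay near the top of the brightness scale, so its difference may be understated. The single marker genes given here were chosen after their values were seen. Melanocyte lineage genes lay the other way, with a median difference of −3.51 and 15 of 19 members at least 2-fold brighter on the MDA-MB-435 array, with MITF, the melanocyte transcription factor, at −2.43. Genes of basal mesenchymal breast lines had a median difference of −0.74, with 9 of 18 at least 2-fold brighter on the MDA-MB-435 array. The mesenchymal filament gene VIM differed by −6.88. In MDA-MB-435 it lay near the top of the brightness scale, so the size of its difference may be understated. Fibroblast genes differed by −0.12 and blood cell genes by 0.11, inside the range of random lists. A label of the second array names MDA-MB-231 for the pre-miR-125b sample, and its other labels name MDA-MB-435. Between its channels the median log2 ratio was −0.12 for luminal genes, 0.32 for melanocyte genes and 0.18 for genes of basal mesenchymal breast lines. Within that array the ratios of the 2 channels had a robust SD of 0.329 in log2 and 0.882% of genes passed 2-fold, close to the MCF-7 array (0.332 and 1.11%). Between the lines the robust SD was 0.781 and 26.7% of genes passed 2-fold. For the second array these values argue against 2 channels from lines as far apart as MCF-7 and MDA-MB-435.

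In MCF-7 at 12 h, 102 of 16031 probes (0.636%) were at least 2-fold higher with pre-miR-125b and 97 (0.605%) at least 2-fold lower. Among genes above background in both channels and brighter than the median probe counted, the lowest was IMPA2 on chromosome 18, an inositol monophosphatase, at −1.52 (2.86-fold lower). It was followed by MTFP1, a mitochondrial fission protein, at −1.40, SLFN11, a regulator of stressed replication forks, at −1.38, LIPA, the lysosomal acid lipase, at −1.32, and ANXA11, an annexin, at −1.25. CLN6, a protein of the endoplasmic reticulum, stood at −1.18, SLC67A2 at −1.16, the receptor LGR6 at −1.13, the transcription factor KLF13 at −1.13, TMEM50A at −1.10, CGN, the tight junction protein cingulin, at −1.10, and HMGB3 at −1.08. The highest within the same brightness limits was PITPNA on chromosome 17, a phosphatidylinositol transfer protein, at 1.43 (2.70-fold higher), then YKT6, a SNARE protein, at 1.39, TIMP3, an inhibitor of metalloproteinases, at 1.37, RERG at 1.25 and ZC3H14 at 1.22, whose other probe gave 0.79. CPLX2 (1.16), SLC4A5 (1.14), TARP (1.13), FOS (1.12), COMMD10 (1.09), SLC19A3 (1.06) and UMPS (1.06) followed; the array file names the CPLX2 probe as CPLX1 and the TARP probe as TRGV9. In 5 of these 12 highest genes (PITPNA, YKT6, TIMP3, RERG and UMPS) the spot lay in blocks 1 to 8, where probes past 2-fold higher were more frequent on both arrays, although blocks 7 and 8 held 0 of them in MCF-7. With a loess curve per block 10 of the 12 lowest and 9 of the 12 highest passed 2-fold; CGN stood at −0.91, HMGB3 at −0.87, CPLX2 at 0.91 and UMPS at 0.79, and COMMD10 came just under it. Of the probes past 2-fold, 18 of the higher and 25 of the lower had 1 channel at the background limit. Median centring without loess gave 164 higher and 69 lower, the authors' ratios 249 and 253, and the stricter brightness filter 17 and 20.

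Reported targets of miR-125b were lower as a group in MCF-7. Of 41 measured members of that list, which was drawn from general knowledge, 28 had negative ratios, 8 were at least 1.5-fold lower and none at least 1.5-fold higher. The median was −0.21, at percentile 0.04 among random lists of like brightness. KLF13 (−1.13), CGN (−1.10, or −0.91 with a loess curve per block), ARID3A, a DNA-binding protein (−0.78), and SGPL1, the sphingosine-1-phosphate lyase (−0.72), were the lowest members. TP53, the p53 gene, was at −0.36, or −0.24 with a loess curve per block. BAK1, a pro-apoptotic BCL2 family member, was at −0.46 and STARD13, a Rho GTPase-activating protein, at −0.24. ETS1 was at −0.15, which became 0.11 with a loess curve per block. Of the receptor tyrosine kinases on the list, ERBB2 was at 0.38 and ERBB3 at −0.25, with the other ERBB3 probe at 0.69. In MDA-MB-435, 28 of 42 measured members were negative, 7 were at least 1.5-fold lower and 3 at least 1.5-fold higher, and the median of −0.10 lay at percentile 4.43, inside the range of random lists. There BAK1 was at −0.76, TP53 at −0.57, or −0.41 with a loess curve per block, and KLF13 at −0.57. ARID3A was at −0.21 and ERBB3 at −0.23 with its other probe at 0.18. ERBB2 was at −0.07, ETS1 at 0.05, CGN at 0.21 and STARD13 at −0.01. SGPL1 was at −0.003, or −0.29 with a loess curve per block. With a loess curve per block the MDA-MB-435 list lay at percentile 1.43, past the limit, and with the median over a gene's probes at 17.5; the difference between the lines was not tested.

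**Figure D1:**
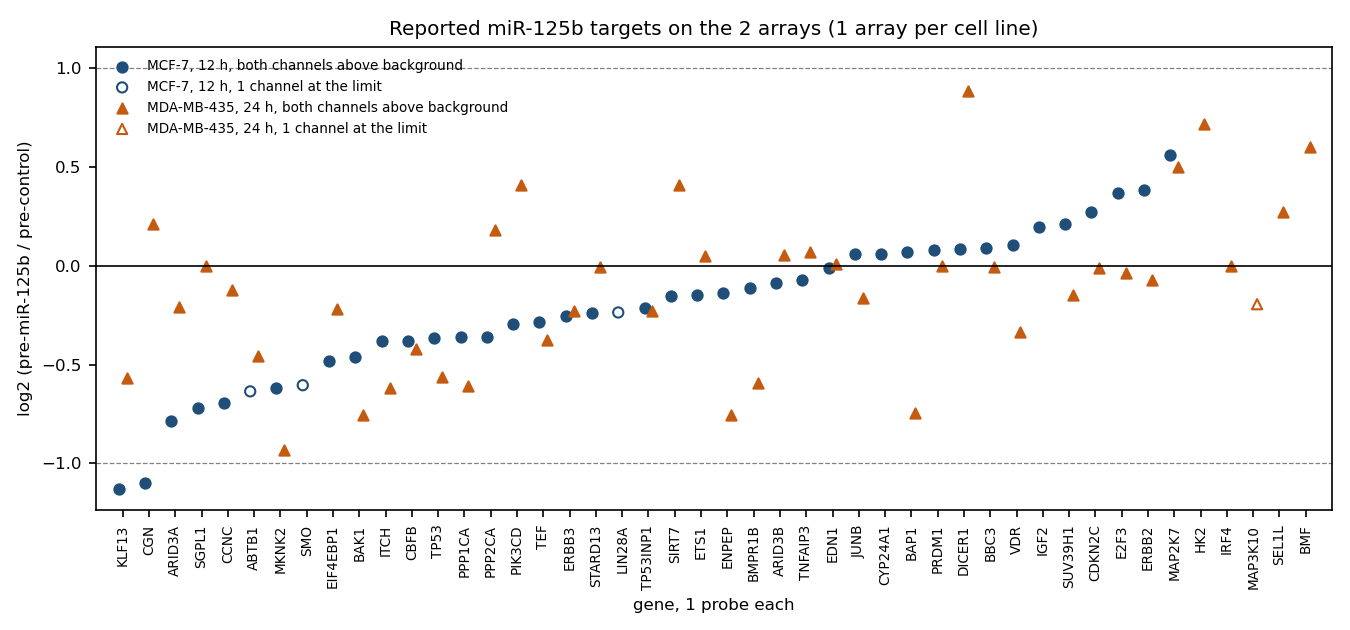
Log2 ratios of pre-miR-125b over pre-control (vertical axis) for the measured members of the reported target list (horizontal axis, ordered by the MCF-7 value), with circles for MCF-7 at 12 h and triangles for MDA-MB-435 at 24 h. Each point is 1 probe on 1 array, open symbols have 1 channel at the background limit, dashed lines mark 2-fold, and 28 of 41 MCF-7 points and 28 of 42 MDA-MB-435 points lie below 0.

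Of the 26 other lists, 3 stood apart as lower and 1 as higher in MCF-7. The BCL2 family and caspase list, the core of the apoptosis machinery, had 25 measured members with a median of −0.32, below all 10000 random lists; 5 members were at least 1.5-fold lower and 2 at least 1.5-fold higher. The lowest were BAD, a pro-apoptotic BCL2 family member (−0.87), CYCS, cytochrome c (−0.76), and the executioner caspases CASP6 (−0.67) and CASP7 (−0.64). Of these members 2, BAK1 and BBC3, are also on the reported target list; without them the median was −0.32 at percentile 0.01. Heat shock genes were higher, with a median of 0.17 at percentile 98.9 over 20 members, 2 at least 1.5-fold higher and 1 at least 1.5-fold lower. The chaperone genes HSP90AA1 (0.66), DNAJB1 (0.59), HSPD1 (0.47) and HSP90AB1 (0.46) led them. The list was mixed, with 7 of its 20 members negative and a mean of 0.09; the HSP70 genes HSPA8 (−0.46) and HSPA1A (−0.31, over 17 spots), named after their values were seen, were lower. Fibroblast markers had a median of −0.44 at percentile 0.12 over 10 members, 3 of them at least 1.5-fold lower, with PDGFRB at −0.82 and FBLN1 at −0.54. TWIST2 (−0.85) and THY1 (−0.64) were at the background limit with pre-miR-125b, and a loess curve per block put them at −0.61 and −0.29. These genes were dim in MCF-7, and under the stricter brightness filter fewer than 8 were left; with the median over a gene's probes the list lay at percentile 3.44, inside the random range. Mesenchymal and migration genes had a median of −0.20 at percentile 1.99 over 18 members, of which 1, the collagenase MMP13 at −0.97, was at least 1.5-fold lower; TWIST1 was at −0.53, TGFBR2 at −0.50, and MMP9, at the background limit with pre-miR-125b, at −0.57, or −0.16 with a loess curve per block. With a loess curve per block this list lay at percentile 10.5, with the authors' ratios at 6.27 and with no filter at 6.73, all inside the random range.

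**Figure D2:**
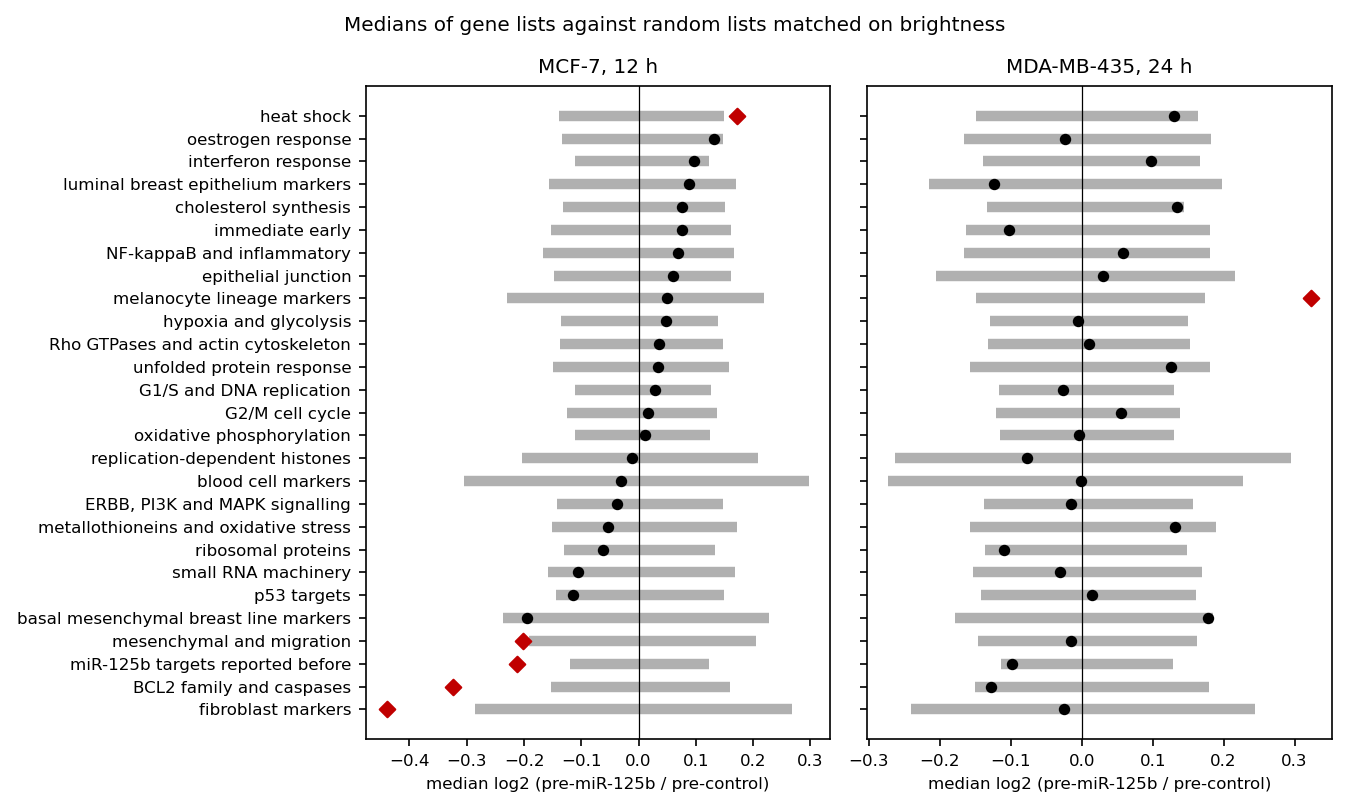
Median log2 ratio of pre-miR-125b over pre-control (horizontal axis) of each gene list (vertical axis) on the MCF-7 array (left) and the MDA-MB-435 array (right), 1 array each. Grey bars span all but the lowest 2.5% and highest 2.5% of 10000 random lists matched on brightness; red diamonds mark lists outside the bar, such as the BCL2 family and caspases at −0.32 in MCF-7 and melanocyte lineage markers at 0.32 in MDA-MB-435.

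In MDA-MB-435 at 24 h, 90 of 15991 probes (0.563%) were at least 2-fold higher with pre-miR-125b and 60 (0.375%) at least 2-fold lower. Within the same brightness limits the lowest gene was ATM on chromosome 11, a kinase of the DNA damage response, at −2.13 (4.39-fold lower), or −1.91 with a loess curve per block. Of its 2 probes, only this 1 was above background on either array. In MCF-7 its pre-miR-125b channel was at the background limit, with a ratio of −0.92, or −0.52 with a loess curve per block. SPICE1, a centriole and spindle protein, stood at −1.39, with its other probe at −0.38, PDIA2 at −1.09 and RAB3D at −1.08, with their other probes at −0.51 and 0.45. IMPA2 (−1.08), the chemokine receptor CXCR3 (−1.08), the phosphatase DUSP3 (−1.07), DOC2A (−1.07), ASB13 (−1.06), GINS4, a replication helicase subunit (−1.06), ATP8B2 (−1.03, with its other probe at −0.28) and MTFP1 (−1.02) completed the 12, of which 6 passed 2-fold with a loess curve per block and 5 with the authors' ratios. The highest was EIF5 on chromosome 14, a translation initiation factor, at 1.67 (3.19-fold higher), and in MCF-7 it was at −0.13. LONRF1 (1.37), ASPH, an aspartate hydroxylase (1.32), the kinase SGK1 (1.29), PTER (1.25), the guidance receptor ROBO1 (1.25) and SEC23A, a vesicle coat protein (1.20), came next. PCNP (1.16), NMD3, an export adaptor of ribosomal subunits (1.16), MIER1 (1.15), PAIP2, a regulator of translation (1.15), and DIMT1, an rRNA methyltransferase (1.14), followed. The melanocyte lineage list was the only other list that stood apart, with a median of 0.32 at percentile 99.98 over 19 members, 3 of them at least 1.5-fold higher. Its leading members were the endothelin receptor EDNRB (0.89), TRPM1 (0.68, with its other probe at −0.06), the transcription factor PAX3 (0.63) and SOX10 (0.52), and a loess curve per block put SOX10 at 0.13 and the list at 0.16, percentile 97.9. Of the 12 highest genes, 8 lay in blocks 1 to 8, and with a loess curve per block 5 of the 12 passed 2-fold and the higher probes numbered 48 against 44 lower. Without blocks 1 to 8, chosen after seeing the data, 33 probes were higher and 57 lower, and the melanocyte list lay at percentile 97.0. The authors' ratios gave 166 higher and 112 lower probes, and the stricter brightness filter 22 and 18.

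Across the 14643 probes counted on both arrays, log2 ratios correlated with Pearson's r = 0.338 and Spearman's rho = 0.328; probes are not independent replicates, and both arrays carried the same dye orientation. Past 2-fold, 10 probes were lower on both arrays, where independent lists would share 0.331, and 2 were higher on both, where they would share 0.487; 1 probe passed 2-fold in opposite directions. The named genes lower on both were IMPA2, MTFP1, SPICE1, IL1B, an inflammatory cytokine (−1.18 in MCF-7 and −1.02 in MDA-MB-435), and COL6A1, a collagen chain (−2.33 and −1.11, with the pre-miR-125b channel at the limit on both). The higher ones were ASPH (1.44 and 1.32) and AIDA (1.01 and 1.13). With a loess curve per block, COL6A1 (−2.27 and −1.08) and ASPH (1.51 and 1.47) were the ones of these past 2-fold on both arrays. AIDA stood at 0.71 and 0.87, IL1B at −0.97 and −0.91, MTFP1 at −0.97 in MDA-MB-435 and SPICE1 at −0.99 in MCF-7, and IMPA2 came just under 2-fold in MDA-MB-435. Of the 12 lowest genes of each array, 10 of the MCF-7 set and 12 of the MDA-MB-435 set had the same sign on the other array; of the highest, 10 and 9 did. Among genes lowest in MCF-7, SLFN11 was at −0.71, LIPA at −0.66, ANXA11 at −0.70 and CLN6 at −0.82 in MDA-MB-435. The caspase and BCL2 family genes that led the MCF-7 list were at −0.34 (BAD), −0.47 (CYCS), −0.58 (CASP6) and −0.56 (CASP7) there, and that list's median was −0.13 at percentile 4.97.

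**Figure D3:**
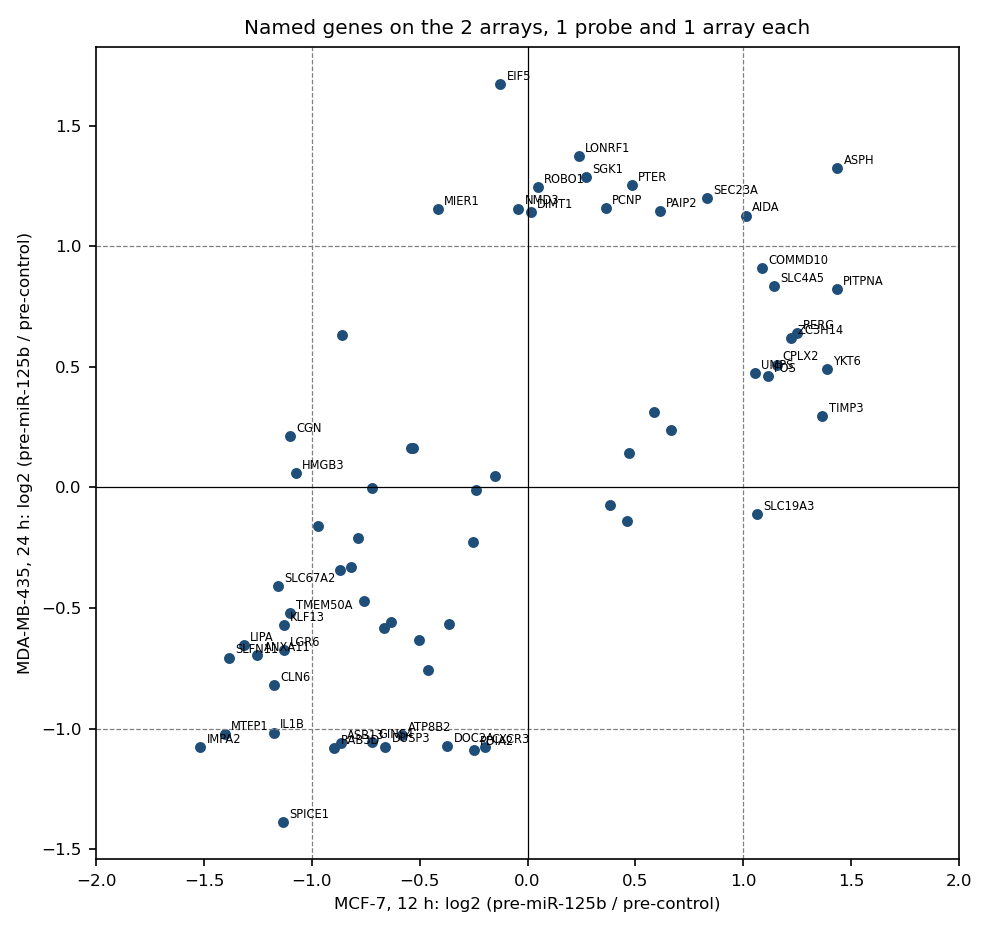
Log2 ratios of pre-miR-125b over pre-control of the named genes that were above background in both channels of both arrays, for MCF-7 at 12 h (horizontal axis) and MDA-MB-435 at 24 h (vertical axis), each point 1 probe on 1 array per line. Dashed lines mark 2-fold; IMPA2 (−1.52 and −1.08) and ASPH (1.44 and 1.32) lie past them on both axes, and EIF5 (−0.13 and 1.67) on the vertical axis alone.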

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

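The tests of slide position and of dye bias on the correlation between arrays were chosen after the result was seen; those on control oligonucleotides and on base composition were set out before their results were seen.

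PAX3 had opposite signs in the cell lines, at −0.86 in MCF-7 and 0.63 in MDA-MB-435, at least 1.5-fold on each array. With 1 array per line the difference was not tested, and time after transfection differed with the line.

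Some yeast spike-in probes, which no comparison of the transfections used, had ratios past 2-fold. In MCF-7, Y3 was at 1.02, Y5 at −2.36, Y6 at 3.85 and Y8 at 1.92. In MDA-MB-435, Y5 was at −2.47, Y6 at 3.44 and Y8 at 1.51. Y6 in MCF-7 and Y5 in MDA-MB-435 were saturated in their brighter channel, and Y6 in MDA-MB-435 was close to it, so the sizes of these ratios were not measurable. The amounts added to each channel are not given in the sources used here.

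Of 559 positions listed as empty, 95 were above the background limit on the MCF-7 array and 95 on the MDA-MB-435 array. They coincided on 60 positions, where independent sets would share 16.1. Intensities over 1000 were seen at 28 and 33 empty positions, 25 of them shared.

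Probes at least 2-fold higher were more frequent in blocks 1 to 8 than elsewhere, 1.18% against 0.522% in MCF-7 and 2.10% against 0.249% in MDA-MB-435, although blocks 7 and 8 held 0 of them in MCF-7. Other blocks, picked after their values were seen, were low. Blocks 19 and 23 had medians of −0.22 and −0.20 in MCF-7 and −0.20 and −0.20 in MDA-MB-435. HMGB3, ANXA11, ATM, DUSP3, ATP8B2, MMP9 and TP53 lay there. Block 15, with MTFP1, CGN, IL1B and THY1, had a median of −0.19 and 10 probes at least 2-fold lower in MCF-7. Position was not tested for these low blocks. Position on the slide was tested on 12 control oligonucleotides printed in every block, the yeast spike-ins, saturated ones included, and the housekeeping genes ACTB, GAPDH, LDHA and RPS9. GAPDH was saturated in both channels on both arrays, so its differences (−0.003 and −0.03) could not show position. The 12 were higher in blocks 1 to 8 by a median of 0.19 in MCF-7 (10 of 12 positive) and 0.25 in MDA-MB-435 (11 of 12 positive), which a position effect would give. The values are in line with position as a source of the excess, and no biological explanation was tested.

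The arrays' log2 ratios correlated although line and time differed. Position was not the whole source, since r was 0.284 after a loess curve per block against 0.338 before. Base composition was not either. Probes with runs of at least 5 G had median ratios of −0.08 in MCF-7 and −0.13 in MDA-MB-435, yet r was 0.265 after base counts and G runs were also regressed out. A response to pre-miR-125b in both lines and a dye bias of single probes cannot be told apart, since 0 arrays had swapped dyes.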

How the results depend on the processing

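Alternatives named as an offset of 50, a limit from DMSO spots, without blocks 1 to 8, and every setting of the seed match in the oligonucleotides were chosen after seeing the data; the others were planned. No paired analysis was possible because each cell line had 1 array. The planned 3′ UTR search, with its site, length, GC and coding sequence alternatives, and the alternative with no background correction were not run. Under the stricter filter and the limit from DMSO spots fewer probes entered, and with no filter more did. Plain ratios differ from the reported ones only where a channel lay under the limit. The shifts in counts with plain ratios thus come from such probes. For every other shift the cause was not tested. Signal over background limits the counts, since 89 of the MCF-7 probes past 2-fold and 56 of the MDA-MB-435 probes were among the dimmest 25% of probes counted.

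Probes at least 2-fold higher and lower in MCF-7 (102 and 97) numbered 339 and 294 with plain ratios, 249 and 253 with the authors' values, 17 and 20 under the stricter filter, 881 and 1090 with no filter, 27 and 26 with the limit from DMSO spots, and 479 and 733 by the rule of local SDs. Median centring gave 164 higher. In MDA-MB-435 (90 and 60) they numbered 237 and 145, 166 and 112, 22 and 18, 684 and 761, 43 and 23, and 501 and 733 under the same alternatives in that order; a loess curve per block gave 48 higher and leaving out blocks 1 to 8 gave 33.

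The reported targets stayed lower in MCF-7 under every alternative run, with medians from −0.25 to −0.13. In MDA-MB-435 they passed the limit with a loess curve per block (−0.11, percentile 1.43), the authors' values (−0.11, 1.63), the stricter filter (−0.19, 0.33), no filter (−0.15, 0.66) and without STARD13 (−0.12, 2.02). They stayed inside the random range with plain ratios (percentile 4.22), an offset of 50 (4.25), median centring (−0.07, 9.37), the DMSO limit (−0.07, 7.35), the median over a gene's probes (−0.05, 17.5) and without blocks 1 to 8 (−0.13, 5.56). Other lists standing apart as higher in MCF-7 numbered 2 in place of 1 with median centring, the authors' values, the stricter filter, the median over probes and without blocks 1 to 8, and 4 with a loess curve per block. In MDA-MB-435 they numbered 4 in place of 1 with a loess curve per block, the authors' values and the DMSO limit, and 2 with plain ratios, no filter and without blocks 1 to 8; lists standing apart as lower numbered 1 in place of 0 with median centring and the DMSO limit and 2 with a loess curve per block and the authors' values.

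Other lists standing apart as lower in MCF-7 (3) numbered from 2 to 4 over the alternatives. In MCF-7 the p53 targets stood apart as lower with a loess curve per block, the authors' values, the stricter filter and the DMSO limit, and oestrogen response genes as higher under 6 alternatives. In MDA-MB-435, cholesterol synthesis genes stood apart as higher under 6 alternatives and basal mesenchymal markers under 4, and ribosomal proteins as lower under 3.

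The correlation between arrays was 0.442 under the stricter filter and 0.174 with no filter. Probes higher on both arrays (2) numbered 17 with plain ratios, 5 with median centring, 15 with the authors' values, 0 under the stricter filter, 91 with no filter, and 1 with the DMSO limit and without blocks 1 to 8. Probes lower on both (10) numbered 26 with plain ratios, 4 with a loess curve per block, 3 under the stricter filter, 164 with no filter and 4 with the DMSO limit. In MCF-7 the probes with a seed match passed the limit as 8mers (−0.18) and without blocks 1 to 8 (−0.11). The cell line markers kept their direction with all channels quantile scaled. Of the values of single genes and lists under each alternative, 1431 were close to the reported value or on the same side of the limit. Another 170 ratios moved by more than the SD between spots, 34 list medians came to stand apart under an alternative and 5 no longer did. No ratio past 2-fold and no list standing apart changed sign. The total of 1431 overstates the agreement. The stricter filter keeps the same ratio of a gene. Plain ratios and no filter do so where both channels lay above the limit. A loess curve per block moved 57 of 202 values and the authors' values moved 63 of 202.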

Other observations

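The test of seed matches and the test of slide position were chosen after the results were seen, as were the single genes named in the first paragraph; the test of base composition on the reported targets was set out before its result was seen.

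Among lists that did not stand apart, some members passed 2-fold. Of the immediate early genes, EGR1 was at 1.73 and FOS at 1.12 in MCF-7 and at 0.66 and 0.46 in MDA-MB-435, while JUN was at −0.26 and −0.42; the list medians were 0.08 and −0.10. The interferon-induced gene MX1 was at 1.16 and 0.53, with list medians of 0.10 on both arrays. In MCF-7, EGR1 and MX1 fell outside the brightness limits used for the highest genes, so they were not named among those. In the small RNA machinery, AGO2 was at −0.15 in MCF-7 and 1.07 in MDA-MB-435 and DICER1 at 0.09 and 0.88, with list medians of −0.11 and −0.03. SLC7A11, the cystine transporter, was at 0.85 and 0.81, with medians of −0.05 and 0.13 for metallothioneins and oxidative stress. Cholesterol synthesis genes had medians of 0.08 and 0.13, with MSMO1 at −0.29 and 0.94 and HMGCS1 at 0.17 and 0.55.

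The other lists had the following medians, MCF-7 first. Oestrogen response genes were at 0.13 and −0.02, p53 targets at −0.11 and 0.01, and NF-kappaB and inflammatory genes at 0.07 and 0.06. G2/M genes were at 0.02 and 0.05, G1/S and DNA replication genes at 0.03 and −0.03, and replication-dependent histones at −0.01 and −0.08. ERBB, PI3K and MAPK signalling genes were at −0.04 and −0.01, Rho GTPases and actin cytoskeleton genes at 0.03 and 0.01, and epithelial junction genes at 0.06 and 0.03. Ribosomal proteins were at −0.06 and −0.11, unfolded protein response genes at 0.03 and 0.13, hypoxia and glycolysis genes at 0.05 and −0.01, and oxidative phosphorylation genes at 0.01 and −0.00. Luminal markers were at 0.09 and −0.12, basal mesenchymal markers at −0.20 and 0.18 and blood cell markers at −0.03 and −0.00. In MDA-MB-435, heat shock genes were at 0.13, fibroblast markers at −0.02 and mesenchymal and migration genes at −0.01; in MCF-7, melanocyte markers were at 0.05.

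The reported targets were lower in MCF-7, and 3 explanations were weighed. Dye bias of single probes was not among them. It cannot be told apart from an effect of the precursor, since the dyes were not swapped. Position on the slide was argued against by a percentile of 0.035 with a loess curve per block, and base composition of the probes by a percentile of 0.04 after base counts and G runs were regressed out. A hypothesis is that pre-miR-125b lowered messages with a seed match, which may show in probes whose own oligonucleotide holds one. In MCF-7 the 215 such probes had a median of −0.04 at percentile 10.3, inside the random range, and in MDA-MB-435 the 218 such probes had a median of −0.10 at percentile 0.04. Seeds of microRNAs that were not transfected gave shifts as well. In MDA-MB-435, miR-26 matches lay at percentile 4.53 among lists matched on brightness, inside the random range, and at 0.545 among lists matched also on GC content, where miR-125b lay at 0.48. Matches of the miR-17 family had a median of 0.08 in MCF-7, above the random range under both matchings. The 7-base match CTCAGGG ranked lowest of 122 sequences with the same bases in MDA-MB-435 and 4 of 123 in MCF-7. Among all 7-base sequences ranked it stood at 121 of 8704 and 436 of 8685, behind G-rich ones. In MDA-MB-435 a miR-26 match stood at 98. The reverse complement of the miR-125b matches lay at percentiles 54.0 and 83.2 there and 97.0 and 98.8 in MCF-7. The 8mers lay at 0.15 and 0.64 in MDA-MB-435 and at 0.87 and 1.42 in MCF-7, below the random range under both matchings. With a loess curve per block, probes with either match lay at percentile 31.9 in MCF-7 and at 0 in MDA-MB-435. Whether the shift in MDA-MB-435 is specific to miR-125b thus stays unsettled. The explanation stays open, also because the oligonucleotides cover a small part of each message and 3′ UTRs were not searched.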
